A study of Mus musculus with 2 samples.

How the data were processed

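MicroRNA sequencing libraries were made from the gastrocnemius, a calf muscle, of 2 female B6CASTF1/J mice, the first-generation cross of C57BL/6 and CAST mice, at 10 days of age. Per the labels, total RNA was the starting material and RNA shorter than 30 bases was selected. The labels number the samples as biological replicates 1 and 2 and describe them as separate animals, and the replicate numbers used here are theirs. Both samples carry the same donor entry in the labels, which was read as an entry for the strain. All samples fall into 1 group, so the design holds no contrast between conditions.

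The deposited files give raw read counts per miRNA gene, with no normalization by the authors. Each file holds an unstranded, a sense and an antisense count for 2202 miRNA genes and 4 summary rows for reads that were unaligned, aligned to several places, outside miRNA genes or ambiguous. Per the descriptions deposited beside the counts, the genome build was mm10 and the annotation was GENCODE M21. The aligner, its version, adapter trimming and filters are not given in the sources used here. Which column is sense and which antisense was read from the layout, known from gene counts of the STAR aligner, and from the totals of the columns. The annotation used here was the same GENCODE release, and all 2202 gene identifiers matched it. It supplied symbols, coordinates, host genes and precursor sequences. A host gene is an annotated gene on the same strand that contains the miRNA gene. A miRNA gene was counted in an exon where it overlaps an exon of any annotated transcript of its host. It may lie in an intron of other transcripts of that host.

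This counting affects the measurements in 3 ways. A gene count sums both arms of a hairpin, so the -5p and -3p miRNAs cannot be told apart. A read that aligned to several places was set aside and counted on no gene, so miRNAs with an identical copy elsewhere are undercounted. Without strand, a read over 2 miRNA genes on opposite strands was ambiguous and dropped, and sense counts avoid this loss. Reads carry no molecular identifiers in these files, so intervals and floors cover counting error only.

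The depth was 8152102 reads in replicate 1 and 10176117 in replicate 2, of which 3510897 (43.1%) and 3949733 (38.8%) were assigned to the sense strand of a miRNA gene. Summary rows stayed out of library totals and tests. Reads aligned to several places were 42.6% and 46.4% of the file, unaligned reads 11.8% and 12.3%, and reads aligned outside miRNA genes 2.55% and 2.52%. Without strand, 6.66% and 6.75% of reads were ambiguous. The limit that a count of 0 allows, 3 counts, was 0.854 CPM in replicate 1 and 0.760 CPM in replicate 2. It covers only reads that can be placed at a single site.

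Counts were scaled here to a total of 1e6 sense reads on miRNA genes per library, abbreviated CPM. Levels are means ± SD of the 2 animals. Shares of a single library have Wilson 95% intervals. A gene was called detected at 2 CPM or more in both libraries. Agreement of the animals was described by Pearson's r of log2(CPM + 1) and Spearman's rho across genes. The spread between animals was the common biological coefficient of variation from edgeR 4.0.16 in R 4.3.3, with TMM factors, an intercept and a minimum of 10 counts in each library. A chi-square test over genes with an expected count of at least 5 asked whether the libraries differed by more than sampling noise, beside 100 simulated pairs of libraries drawn from shared proportions.

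The 2 libraries were compared gene by gene with a two-sided exact conditional binomial test of the counts given the library totals. Benjamini-Hochberg adjustment ran over genes with at least 10 counts in both libraries together. A call needed an adjusted p under 0.05 and a difference of at least 2-fold in CPM. Log2 ratios are replicate 2 over replicate 1, with 0.5 added to each count. Such a test compares these libraries, not conditions, and has no replicate behind it.

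In all, 19 gene lists covering muscle, family, cluster and cell type miRNAs were written before the data were examined. Of their symbols, 168 matched by symbol, 14 by a RefSeq synonym and 3 not at all, and the remainder were second names of genes already matched. For lists with at least 3 tested members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 10 bins of mean expression. Neighbouring miRNA genes at most 10 kb apart on the same strand formed a cluster. Copies were genes whose symbols differ only in a final copy number after a hyphen, with at least 2 such genes in a group, and the share of 22-base windows of each precursor that occur in another annotated precursor was computed. Both strands were searched, and precursors that overlap the gene itself were left out of the search. A genome sequence was not used here, so this share misses identical sequence outside annotated precursors.

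Named genes were fixed by rule before the data were examined. They were the 20 genes with the highest mean CPM, up to 4 members per list with the highest mean CPM and the striated muscle list in full, the 5 genes with the largest fold in each direction among called genes with a mean of at least 10 CPM, and the members of the 5 copy groups with the highest summed CPM. Genes outside this rule are named where a small count or a cluster made it necessary, and the text says so.

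The comparison was tested on simulated data with 200 changed genes, and 380 genes, changed or not, passed the count filter. It recovered 92.2% of 64 genes changed 3-fold and 96.8% of 63 genes changed 6-fold, and called 0 of 191 unchanged genes. The other genes were changed 1.5-fold, below the limit of a call, and were not scored. Both simulated libraries held counting noise alone, so these rates do not cover the spread between animals in the real pair. A simulated coefficient of variation of 0.15 came back as 0.146 over 323 genes. Alternatives covered unstranded counts, other denominators, each replicate left out, TMM and DESeq2 1.42.0 size factors, other count filters, fold thresholds, detection limits, pseudocounts, cluster distances and window lengths. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. As tests of an explanation, read depth, counting error in the called genes, a linear GC trend, scaling by Mir206, muscle maturity and whether copies sit on the same side of their cluster partners in both libraries were written and then dropped. They moved too little, could not tell the explanations apart, or had an outcome fixed by construction or by the choice of genes. The thinned library, the removed GC trend and the totals without Mir206 remain as alternative settings. The deposited descriptions of the files hold no measurements and gave only the build and annotation.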

Results

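MicroRNAs of the gastrocnemius were profiled in 2 female B6CASTF1/J mice at 10 days of age. The labels describe a single tissue, sex and age, so the data give the abundance of each miRNA gene, the spread between the animals and the differences between the 2 libraries. Sense reads on miRNA genes numbered 3510897 in replicate 1 and 3949733 in replicate 2. All levels are counts per 1e6 of these reads (CPM), given as mean ± SD with n = 2 animals, and coordinates are from build mm10.

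Among reads placed at a single site, the most abundant miRNA gene was Mir206, a miRNA known from skeletal muscle, at 105606 ± 14626 CPM. It was followed by Mir378a at 85870 ± 12007 CPM, Mir127 at 82490 ± 1028 CPM, Mir411 at 61091 ± 1491 CPM and Mirlet7i at 53597 ± 52.4 CPM. These 5 genes held 38.9% ± 0.0153 of the reads, the first 10 held 56.2% ± 0.00839 and the first 20 held 74.7% ± 0.785. Of 2202 annotated miRNA genes, 332 reached 2 CPM in both animals. In both animals 77 genes held at least 0.1% of the reads and 21 held at least 1%. No read fell on 1511 genes in either library. Where reads can be placed at a single site, this allows up to 0.854 CPM in replicate 1 and 0.760 CPM in replicate 2. For genes with an identical copy a count of 0 sets no such limit.

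The leading genes lie in different kinds of host. Mir206 (ENSMUSG00000065559.1, chromosome 1, 20679010 to 20679082, plus strand) is in an exon of the lincRNA Gm28653, and its precursor of 73 bases reads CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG. Mir378a (ENSMUSG00000105200.1, chromosome 18, 61397835 to 61397900, minus strand) is in an intron of Ppargc1b, which encodes a coactivator of mitochondrial gene expression. Its precursor of 66 bases reads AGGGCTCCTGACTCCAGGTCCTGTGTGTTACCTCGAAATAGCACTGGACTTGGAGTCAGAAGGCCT. Mir127 (ENSMUSG00000070076.2, chromosome 12, 109592846 to 109592915, plus strand) and Mir411 (ENSMUSG00000065477.3, chromosome 12, 109710175 to 109710256, plus strand) have no annotated host on their strand. Mirlet7i (ENSMUSG00000065406.3, chromosome 10, 122985640 to 122985724, minus strand) is in an exon of the transcribed pseudogene D630033A02Rik. Over all 332 detected genes, 148 in introns held 33.2% of the reads and 109 without a host on their strand held 36.7%. The 75 that overlap an exon of any transcript of their host held 30.0%.

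**Figure D1:**
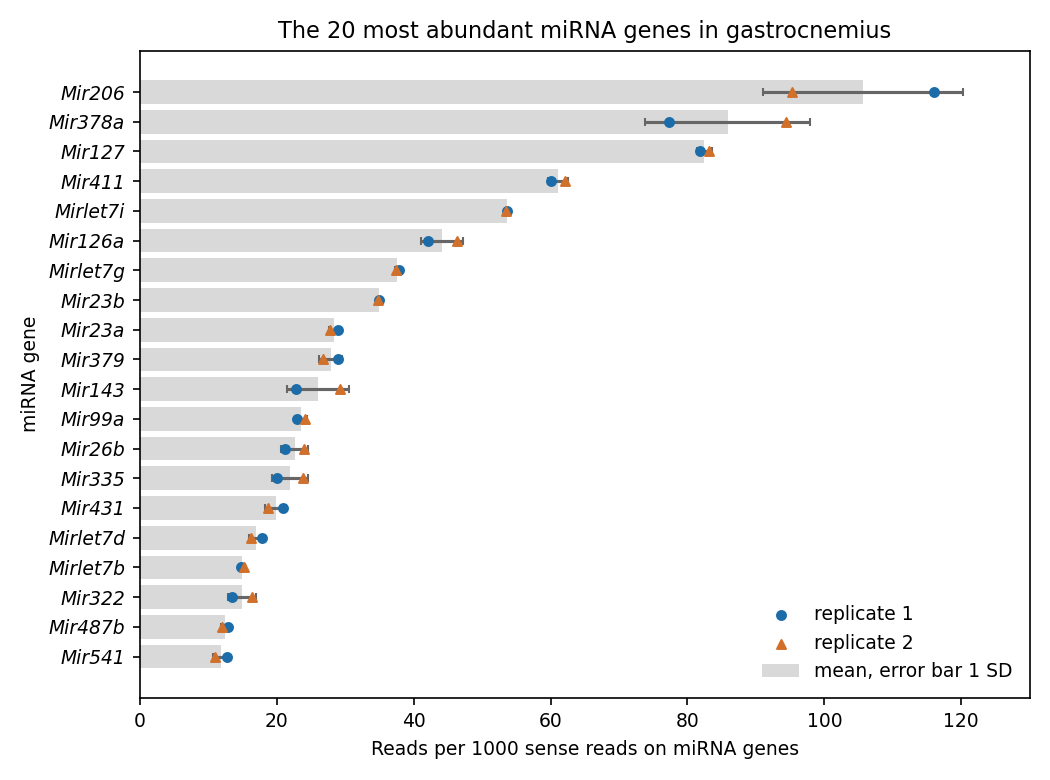
The 20 miRNA genes with the highest mean level, from Mir206 to Mir541. The x axis gives the share of sense reads on miRNA genes in per mille, grey bars the mean of 2 animals with error bars of 1 SD, circles replicate 1 and triangles replicate 2. Mir206, Mir378a and Mir143 show the widest gaps between the animals for their level, and the largest fold among the 20 genes was 1.28.

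The rest of the 20 most abundant genes included several with known cell types or loci. Mir126a, a miRNA of endothelial cells, stood at 44175 ± 3025 CPM. It lies in Egfl7, an endothelial gene, and overlaps an exon of an annotated transcript of it (chromosome 2, 26591357 to 26591429). Mir143, known from smooth muscle and stroma, stood at 25998 ± 4515 CPM, and Mir335, in an intron of the imprinted gene Mest, at 21942 ± 2611 CPM. Mir23b and Mir23a reached 34918 ± 134 and 28409 ± 804 CPM. Mirlet7g reached 37634 ± 385 CPM, Mirlet7d 17045 ± 1067 CPM and Mirlet7b 14998 ± 334 CPM. Mir99a reached 23562 ± 893 CPM, Mir26b 22658 ± 1966 CPM and Mir322 14923 ± 1989 CPM. The remaining 4 genes belong to the Dlk1-Dio3 region on chromosome 12, namely Mir379 (27877 ± 1633 CPM), Mir431 (19858 ± 1530 CPM), Mir487b (12463 ± 628 CPM) and Mir541 (11867 ± 1151 CPM). None of the 20 genes shared a 22-base window with an annotated precursor at another place, and 8 of them, among them Mir378a, Mir411 and Mirlet7i, shared at least 1 window of 18 bases.

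Among striated muscle miRNAs, Mir206 held 99.3% of the reads of the list. The list together held 10.6% ± 1.45 of all reads, 11.7% in replicate 1 (Wilson 95% interval 11.6% to 11.7%) and 9.61% in replicate 2 (9.58% to 9.64%). Mir499, encoded in a slow myosin gene, stood at 339.8 ± 5.66 CPM, Mir208b, likewise in a slow myosin gene, at 101.4 ± 26.6 CPM and Mir486 at 212.6 ± 32.4 CPM. Counts of the muscle miRNAs miR-1 and miR-133 were low. Mir1a-2 stood at 77.43 ± 14.03 CPM, Mir1a-1 at 3.61 ± 0.269 CPM, Mir133a-1 at 4.07 ± 2.13 CPM, Mir133a-2 at 1.04 ± 0.671 CPM and Mir133b at 30.8 ± 4.83 CPM. Mir3107, on the strand opposite Mir486, stood at 8.07 ± 0.671 CPM, Mir208a at 1.60 ± 0.246 CPM and Mir1b at 1.03 ± 1.05 CPM. Mir133c had 0 reads in either library.

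The low counts of miR-1 and miR-133 carry a counting limit, because reads that match several places were set aside. Mir1a-1 and Mir1a-2 share a stretch of 28 bases, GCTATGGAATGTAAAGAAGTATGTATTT, and Mir133a-1 and Mir133a-2 one of 31 bases, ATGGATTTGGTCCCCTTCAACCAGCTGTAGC. Mir133b shares 21 bases with both Mir133a copies, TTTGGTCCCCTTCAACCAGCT. The longest stretch common to Mir1a-2 and Mir206 is 13 bases, CTATGGAATGTAA. In Mir486, 22 bases, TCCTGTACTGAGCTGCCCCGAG, recur as their own reverse complement within the precursor, so such reads match both strands of that locus. The levels of these genes are therefore uncertain and cannot be ranked against Mir206.

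The Dlk1-Dio3 imprinted region, whose miRNAs are expressed from the maternal chromosome, held the largest share of any list, 29.9% ± 0.931 of the counted reads. Reads aligned to several places, 42.6% and 46.4% of the file in replicates 1 and 2, were counted on no gene. On this list, 4 of 58 annotated genes share a window with another precursor. For striated muscle it is 5 of 13 genes, and for let-7 it is 6 of 14. The lists may therefore have lost reads unequally, and their order holds for counted reads only. Of the 58 genes on the Dlk1-Dio3 list, 50 were detected, 49 of them on the plus strand, between 109563692 and 109747960 on chromosome 12. Detected in this span but not on the list, and named after their values were seen, were Mir3544 on the minus strand (34.8 ± 9.15 CPM), Mir1188 (28.3 ± 2.73 CPM) and Gm27379 (4.19 ± 0.917 CPM). Levels of the 50 genes ran from 2.93 to 82490 CPM, and 28 held at least 0.1% of the reads on average. Neighbours at most 10 kb apart formed a cluster from Mir770 to Mir136 with 13.7% ± 0.388 of the reads and a cluster from Mir379 to Mir3072 with 15.8% ± 0.532.

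**Figure D2:**
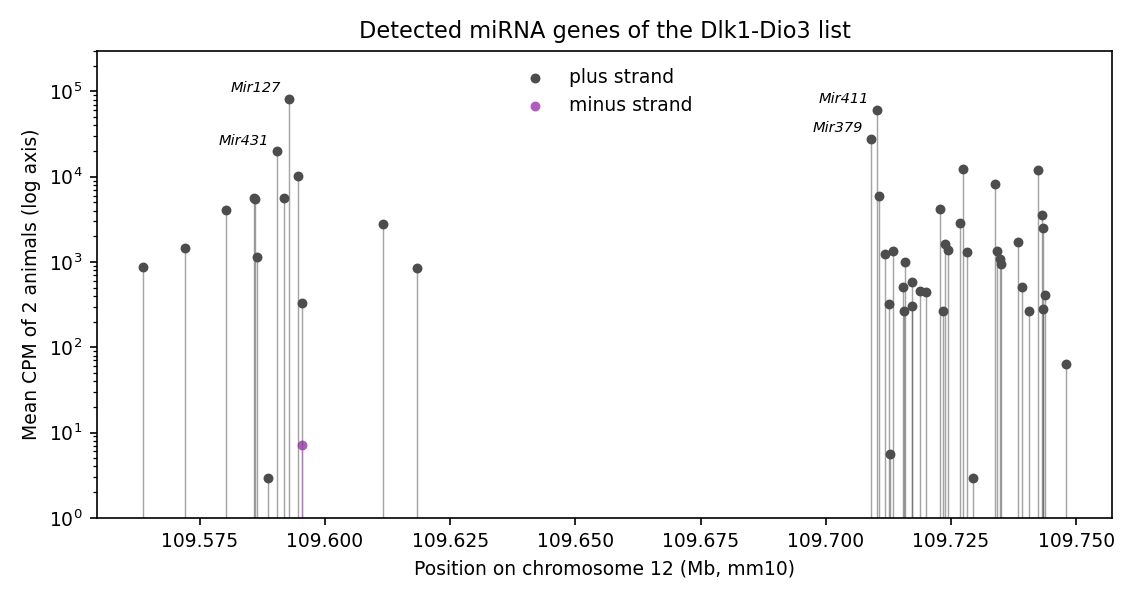
Detected miRNA genes of the Dlk1-Dio3 list by position on chromosome 12 (x axis, Mb, mm10) and mean level of 2 animals (y axis, CPM, log axis), with grey points on the plus strand and the purple point on the minus strand. The 50 genes span 2.93 to 82490 CPM, and Mir127, Mir411, Mir379 and Mir431 stand highest.

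The let-7 family, known to rise as tissues differentiate, held 13.2% ± 0.142 of the counted reads with 13 of 14 genes detected. Mirlet7i and Mirlet7g had the highest counts. Of the 14 genes, 6 share windows with another precursor, among them Mirlet7a-1, Mirlet7c-1 and Mirlet7f-1, so that their reads may have been set aside. The order of the genes within the let-7 family and the share of the family are therefore uncertain. The miR-30 family held 1.78% ± 0.202, with Mir30d at 8153 ± 702 CPM, Mir30a at 6619 ± 834 CPM, Mir30e at 2843 ± 463 CPM and Mir30b at 121.3 ± 7.16 CPM. The miR-10 family and its Hox cluster neighbours held 1.63% ± 0.0464, with Mir196b at 7730 ± 514 CPM, Mir10b at 4757 ± 26.3 CPM, Mir10a at 2497 ± 184 CPM and Mir196a-2 at 967.7 ± 56.2 CPM. The miR-17-92 family clusters, known from proliferating cells, held 0.602% ± 1.85e-05, with Mir17 at 1928 ± 9.08 CPM, Mir93 at 1378 ± 64.2 CPM, Mir20a at 802.8 ± 36.9 CPM and Mir92-1 at 755.2 ± 129 CPM. The miR-29 family held 0.0164% ± 0.00273, with Mir29a at 120.2 CPM (106.8 and 133.7 CPM in replicates 1 and 2) and Mir29c at 40.3 ± 7.83 CPM. Its copies Mir29b-1 and Mir29b-2 each stood at 1.87 ± 0.224 CPM and share windows with each other. At the Igf2/H19 locus, Mir483 stood at 4400 ± 1001 CPM and Mir675 at 40.8 ± 5.33 CPM, together 0.444% ± 0.0995 of the reads.

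Lists for other cell types covered the tissues that dissected muscle could hold. The endothelial list held 4.42% ± 0.303 of the reads, all of them on Mir126a. The smooth muscle and stroma list held 2.67% ± 0.453, nearly all on Mir143, with Mir145a at 688.3 ± 18.8 CPM. The mesenchymal list of miR-199 and Mir214 held 0.346% ± 0.0805, with Mir214 at 3341 ± 792 CPM. Its other members Mir199b (74.1 ± 3.13 CPM), Mir199a-2 (48.4 ± 10.1 CPM) and Mir199a-1 (0.269 ± 0.0224 CPM) share windows with one another. Erythroid miRNAs held 0.197% ± 0.0142, with Mir451a at 1811 ± 141 CPM and Mir144 at 154.5 ± 1.10 CPM. Leukocyte miRNAs held 0.104% ± 0.00878, with Mir146 at 338.0 ± 25.1 CPM, Mir150 at 278.8 ± 7.27 CPM, Mir155 at 183.2 ± 3.72 CPM and Mir142 at 129.6 ± 29.4 CPM.

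The neural, liver, epithelial, sensory organ, gut and stem cell lists held smaller shares. Of these, dissected muscle could also hold neural, glial and epithelial cells. Neural and glial miRNAs held 0.0314% ± 0.00901, almost all on Mir338, a miRNA of oligodendrocytes and neurons, at 304.9 ± 87.6 CPM. In that list Mir219a-1 stood at 4.30 ± 0.358 CPM, Mir219a-2 at 3.02 ± 1.45 CPM and Mir9-3 at 0.886 ± 1.25 CPM, and the Mir9, Mir124a and Mir219 genes share windows with copies, so that their reads may have been set aside. The liver miRNA Mir122 stood at 333.4 ± 223 CPM. Epithelial miRNAs held 0.0161% ± 0.00509, with Mir203 at 112.7 ± 26.2 CPM, Mir205 at 13.0 ± 11.9 CPM, Mir200c at 12.6 ± 6.36 CPM and Mir429 at 10.6 ± 2.77 CPM. The miR-183 cluster of sensory organs held 0.00634% ± 0.00155, with Mir182 at 40.1 ± 9.02 CPM, Mir183 at 23.1 ± 6.85 CPM and Mir96 at 0.253 ± 0.358 CPM. Gut and pancreas miRNAs held 0.00353% ± 0.000369, with Mir192 at 15.5 ± 3.00 CPM, Mir375 at 6.49 ± 1.92 CPM, Mir194-2 at 5.51 ± 0.269 CPM and Mir217 at 3.09 ± 0.0671 CPM. Mir194-2 shares a window with its copy Mir194-1. Of 14 pluripotent stem cell miRNAs, 0 were detected in both animals. Their highest members were Mir302b and Mir302d at 0.949 ± 0.269 CPM each, then Mir302a at 0.854 ± 1.21 CPM and Mir292 at 0.142 ± 0.201 CPM.

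**Figure D3:**
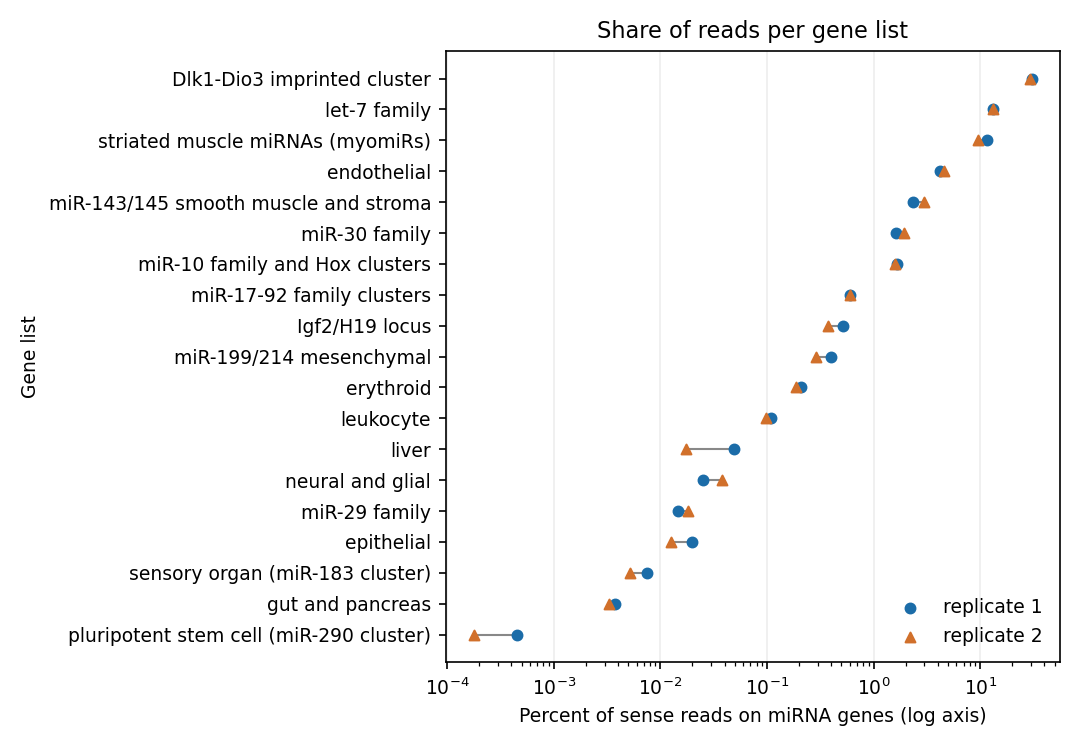
Percent of sense reads on miRNA genes (x axis, log axis) for each of the 19 gene lists (y axis), with circles for replicate 1 and triangles for replicate 2. Shares run from 29.9% for the Dlk1-Dio3 region to 0.000316% for the pluripotent stem cell list as means of the animals, and the liver, epithelial and neural lists show some of the wider gaps.

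Members of a genomic cluster differed widely in counts, and the lowest member often shared sequence with another gene. In 43 clusters with at least 2 detected genes, 153 genes in all, the highest member exceeded the lowest by a median of 17.9-fold, by over 10-fold in 24 clusters and by over 100-fold in 7. The lowest member shared a 22-base window with another precursor in 14 of the 24 clusters and in 5 of the 7, among them those of Mir24-1 and Mir24-2, named after their values were seen. The share of all detected cluster members with such a window was not computed beside this. Over the 25 clusters left among genes with no shared window of 18 bases, a choice made after seeing the data, the median was 4.94-fold, with 10 clusters over 10-fold and 2 over 100-fold. Leaving out members can only lower or keep the range of a cluster, and clusters with fewer than 2 genes left dropped out. The fall therefore cannot show how much of the range comes from shared sequence.

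Multi-copy genes held few of the counted reads. The 53 groups of copies, 138 genes, held 1.02% of reads, and 136 of these genes shared at least 1 window of 22 bases with another precursor. All 1032 annotated genes with such a window held 1.59% of reads. In the group with the highest sum, Mirlet7f-2 stood at 2601 ± 88.8 CPM and Mirlet7f-1 at 175.5 ± 10.8 CPM. Mir128-1 stood at 1151 ± 165 CPM and Mir128-2 at 352.9 ± 2.44 CPM, Mir16-1 at 823.3 ± 21.5 CPM and Mir16-2 at 179.5 ± 3.94 CPM. Mir196a-2 exceeded Mir196a-1 (9.83 ± 1.01 CPM), and Mir92-1 exceeded Mir92-2 (14.9 ± 0.0896 CPM). Where on the hairpin the remaining reads lie cannot be read from counts per gene, so these values are no measure of the shared miRNA.

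The reads were strand-specific. Over genes with no miRNA gene on the opposite strand, antisense reads numbered 33 in replicate 1 and 44 in replicate 2, or 0.00111% (Wilson 95% interval 0.000792% to 0.00156%) and 0.00135% (0.00100% to 0.00181%). The 64 genes with a miRNA gene on the opposite strand, among them Mir378a and Mir126a, held 16.4% of sense reads, and without strand such reads were ambiguous. Counting without strand therefore left the endothelial list with 0.000142%, the neural and glial list with 0.000124% and the erythroid list with 0.0185% of the reads.

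The animals gave closely matching profiles. Across 384 genes with at least 2 CPM in at least 1 library, Pearson's r of log2(CPM + 1) was 0.988 and Spearman's rho was 0.979, both across genes, which are not independent replicates. Of the 332 detected genes, 315 (94.9%) lay within 2-fold and 287 (86.4%) within 1.5-fold. The common biological coefficient of variation was 0.188 over 320 genes. The libraries nevertheless differed by far more than sampling noise. The chi-square statistic was 34945 over 386 genes, 90.8 per degree of freedom, against at most 1.21 in 100 simulated pairs. Repeated preparations of the same RNA would also exceed counting noise, so the reading as separate animals rests on the labels alone.

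Few genes differed by 2-fold or more between the libraries, and those were of low abundance. Of 395 genes tested, 28 passed the exact binomial test and the 2-fold limit, 13 higher in replicate 2 and 15 higher in replicate 1, and together they held 0.0650% of the reads. Without a fold limit, 163 genes had an adjusted p under 0.05. Among the 20 most abundant genes 18 did so, and the largest fold was 1.28, for Mir143. The comparison is between these 2 libraries, each of a single animal.

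Higher in replicate 2 were Mir760 (7.79-fold, 95% interval 5.14 to 12.3, exact adjusted p = 4.59e-34), Mir383 in an intron of Sgcz (6.97-fold, 4.31 to 11.9) and Mir137, a miRNA known from neurons (3.70-fold, 3.11 to 4.42, exact adjusted p = 6.40e-61). Mir92b (3.30-fold, 2.26 to 4.94) and Mir7b (2.44-fold, 1.51 to 4.08), both known from nervous tissue, were also higher in replicate 2. Mir137 had 161 and 670 reads in replicates 1 and 2 (chromosome 3, 118433857 to 118433929, in an exon of Gm26871). Mir760 had 25 and 219 reads (chromosome 3, 122293585 to 122293703), and Mir383 had 19 and 149 (chromosome 8, 38252133 to 38252202).

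Higher in replicate 1 were Mir6240 (8.85-fold, 95% interval 5.15 to 16.3), the epithelial miRNAs Mir205 (4.69-fold, 2.77 to 8.33) and Mir200c (2.11-fold, 1.35 to 3.35), and the liver miRNA Mir122 (2.79-fold, 2.56 to 3.06, exact adjusted p = 4.17e-127). Mir122 had 1724 and 694 reads in replicates 1 and 2 (chromosome 18, 65248861 to 65248926, in an exon of AC157910.3). These were the 4 called genes of at least 10 CPM on average in that direction, against 5 higher in replicate 2. In both directions the intervals cover counting error only.

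**Figure D4:**
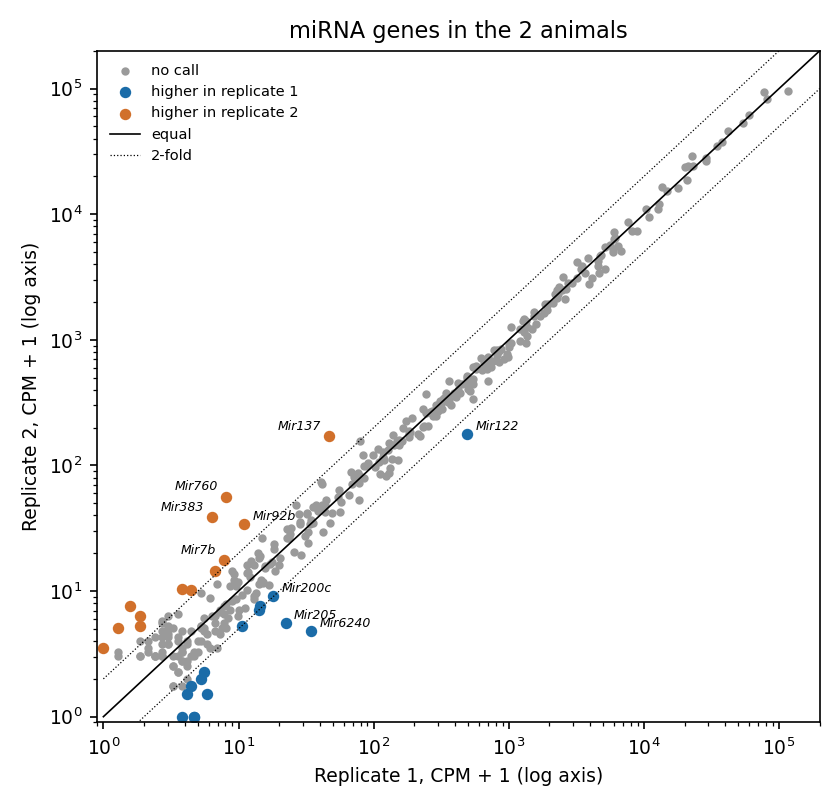
Level of each miRNA gene with at least 2 CPM in at least 1 library, in replicate 1 (x axis) and replicate 2 (y axis), both as CPM + 1 on log axes. The solid line marks equal levels and dotted lines 2-fold, and coloured points are called genes, the 9 with a mean of at least 10 CPM being named. Called genes sit at low levels, with Mir122 the highest at a mean of 333.4 CPM.

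As groups, 3 lists lay outside the middle 95% of random lists matched on expression, as a description of these 2 libraries. Dlk1-Dio3 miRNAs were lower in replicate 2 in 38 of 52 tested genes, with a median log2 ratio of -0.16 (percentile 0.01, random lists -0.12 to 0.01). Of these, 32 were lower and 6 higher at an adjusted p under 0.05. Only Mir299b, named after its value was seen, passed the 2-fold limit, over all genes tested and adjusted over the list alone (1 gene each). Mir127 and Mir411 had log2 ratios of 0.03 and 0.05, and Mir431 of -0.16. Many Dlk1-Dio3 genes are neighbours in the same clusters and may vary together, whereas random lists draw genes from many loci. The range of random lists may therefore be too narrow, and the percentile and the count of lower genes do not measure significance.

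Striated muscle miRNAs had a median log2 ratio of 0.29 (percentile 99.6, random lists -0.29 to 0.18), with 8 of 10 tested genes higher in replicate 2. The summed share of the list moved the other way, because Mir206 had a log2 ratio of -0.28. At an adjusted p under 0.05, 3 genes were higher in replicate 2, namely Mir486, Mir208b (1.46-fold) and Mir1a-2, and Mir206 was lower. The count past the 2-fold limit was 0, also when adjusted over the list alone. The position of this list outside random lists was lost with unstranded counts (median 0.31, random lists -0.36 to 0.31). Mir206 and Mir133b are cluster neighbours, as are Mir1a-2 and Mir133a-1, so the range of random lists may be too narrow for this list too.

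Epithelial miRNAs had a median log2 ratio of -0.80 (percentile 0.70, random lists -0.59 to 0.52), with 5 of 6 tested genes lower in replicate 2. Mir205, Mir200c and Mir200b, the last named after its value was seen, passed the 2-fold limit, 3 genes over all genes tested and 3 adjusted over the list alone. Without a count filter the median was -0.54, at the edge of random lists. Mir429 and Mir200b are cluster neighbours and may vary together, so the range of random lists may be too narrow here as well.

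The other lists with at least 3 tested genes lay inside the range of random lists. The miR-30 family had a median of 0.22 (percentile 96.8) with 6 of 6 genes higher in replicate 2, of which 3 had an adjusted p under 0.05. The miR-29 family had a median of 0.27 (percentile 75.8). The mesenchymal list had a median of -0.43 (percentile 3.22), with Mir214 1.40-fold lower in replicate 2. Medians were -0.06 for let-7 (percentile 25.95), 0.07 for miR-17-92 (percentile 86.7), -0.13 for miR-10 and Hox neighbours (percentile 21.9) and -0.15 for leukocyte miRNAs (percentile 8.71). Neural and glial miRNAs had a median of 0.59 (percentile 93.5) over 3 genes, with Mir338 1.51-fold higher in replicate 2. Gut and pancreas miRNAs had a median of -0.10 (percentile 49.5), and in that list Mir215, named after its value was seen, passed the 2-fold limit, over all genes and adjusted over the list alone (1 gene each). Lists with fewer than 3 tested genes are described by their shares alone. The Igf2/H19 share was 0.514% and 0.374% in replicates 1 and 2, and the Mir143 and Mir145a share 2.35% and 2.99%.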

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

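The test in this part was chosen after the low counts of multi-copy genes were seen. Apart from that test, which uses the sense counts of genes, the values here come from reads that no comparison uses. Those values exceed the limit that a count of 0 allows. With a single group of 2 animals, no sample was tested for standing apart and no difference between groups exists.

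Reads aligned to several places made up 42.6% of the file in replicate 1 and 46.4% in replicate 2. In replicate 2 they outnumbered the sense reads on miRNA genes, 4718603 against 3949733. Reads aligned outside miRNA genes made up 2.55% and 2.52% of the file. Antisense reads over genes with no miRNA gene on the opposite strand numbered 33 in replicate 1 and 44 in replicate 2.

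Many genes that share sequence with a copy had few reads, among them Mir1a and Mir133a, though not all, since Mirlet7f-2 and Mir16-1 exceeded their cluster partners. The counting set aside reads that aligned to several copies, so a loss from these genes follows from the method, and its size is not known. Against partners in the same cluster without a shared 22-base window, the genes with a shared window had a median log2 difference of -4.83 over 23 clusters (quartiles -5.99 and -0.47). With clusters joined where their copies share a window, the median was -2.63 over 15 groups, and they were lower in 12 of these, a tie counting as not lower (exact two-sided sign test, p = 0.0352). This describes the low counts that prompted it. How much of them comes from reads set aside and how much from truly low expression stays open. No biological explanation was tested, since the design has a single group.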

How the results depend on the processing

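Of the alternatives here, list medians with the GC trend removed or with totals without Mir206, the thinned library, the muscle list without Mir206 and the clusters of genes without shared windows were chosen after seeing the data, and all others were planned. The share of the 20 most abundant genes, 74.7%, moved by more than 1 SD to 73.8% with unstranded counts, 30.6% of all reads in the file and 71.7% without Mir206. In the same order, the muscle list moved from 10.6% to 12.7%, 4.38% and 0.0873%, let-7 from 13.2% to 15.4%, 5.41% and 14.8%, and Dlk1-Dio3 from 29.9% to 33.4%, 12.3% and 33.4%. With Mir206 taken out of the muscle list alone, 0.0781% remained. These shifts follow from the changed denominator, the reads dropped as ambiguous or, for the muscle list and the 20 genes, the removal of Mir206 itself. Single libraries gave 74.1% to 75.3% for the 20 genes, 9.61% to 11.7% for the muscle list, 13.1% to 13.3% for let-7, 29.2% to 30.6% for Dlk1-Dio3 and 352 to 364 detected genes. Pearson's r of 0.988 became 0.985 with a pseudocount of 0.5, 0.994 with 5, 0.991 over all genes with a count and 0.995 at 10 CPM or more in both libraries, while Spearman's rho of 0.979 fell to 0.901 over all genes with a count and was 0.994 at 10 CPM or more. The coefficient of variation of 0.188 became 0.207 with no filter. The count of 28 called genes became 13 with at least 50 counts in both libraries together, since fewer genes (287) were tested, and all 13 were among the 28. Under the other settings of filter, scaling, strand, depth and fold it ran from 20 to 37. Of the list medians, the muscle list with unstranded counts (0.31) and the epithelial list with no filter (-0.54) no longer lay outside random lists, and the let-7 median turned from -0.06 to 0.0125 with unstranded counts. The cause was not tested. The 43 clusters became 25 among genes with no shared 18-base window, since fewer genes remained. The detected genes (256 to 381), clusters under other distances (41 to 47), copies with a shared window (102 to 136) and the chi-square per degree of freedom (142 with at least 50 counts in each library) kept their side of every limit. Of 291 alternative values, 50 of the main results stayed within their limits, 18 moved past them and 4 weakened. Of the less prominent ones 149 stayed within their limits and 1 reversed. Another 69 of these moved by more than 1 SD, 40 of them levels of the 20 most abundant genes. No paired analysis was possible because there is a single group. Leaving out a replicate gave no value for results that compare the 2 libraries. With 2 animals, leaving out either moves a mean by less than 1 SD by construction, so that setting says nothing of stability. Its shares and levels are nevertheless counted among the values that stayed within their limits.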

Other observations

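Of the tests in this part, those of liver RNA and of GC content were chosen after the result was seen. The list of nervous tissue miRNAs was written after the called genes but before its own values were examined, and the test of shared reads in the Dlk1-Dio3 region was also written before its value was seen.

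All called genes with a mean under 10 CPM are listed here, a choice made after their values were seen, and their hosts were not tested as a group. Higher in replicate 2 were Mir490, in an intron of Chrm2, with 20 and 53 reads in replicates 1 and 2, Mir6540, in an intron of Gap43, with 10 and 37, Mir129-2 with 12 and 36, and Mir1224, in an intron of Vwa5b2, with 2 and 26. So were Mir346, in an intron of Grid1, with 3 and 21, Mir384 with 3 and 17, Gm23450, in an exon of Cacng8, with 1 and 16, and Mir873a, in an intron of Lingo2, with 0 and 10. Higher in replicate 1 were Mir3074-1, in an intron of Fancc, with 47 and 26, Mir200b, in an intron of Ttll10, with 46 and 24, Mir6945, in an exon of Pdlim7, with 34 and 17, and Mir6538, in an intron of Rnf144a, with 17 and 2. So were Mir34b with 16 and 5, Mir215 with 15 and 4, Mir3572, in an exon of Cnot3, with 13 and 0, Mir201 with 13 and 0, Mir299b with 12 and 3, Mir6715, in an exon of Tectb, with 11 and 2, and Mir5131, in an exon of Ddhd1, with 10 and 0.

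More nervous tissue in the sample of replicate 2 may account for part of the genes called higher there, such as Mir137. Over 8 tested genes of a list of 13 nervous tissue miRNAs outside the calls, the median log2 ratio was 0.73, above the middle 95% of random lists (-0.48 to 0.66, percentile 98.3), with 7 of 8 higher in replicate 2, though only Mir132 and Mir598 at an adjusted p under 0.05 and Mir1298 by no more than a log2 ratio of 0.01. Its most abundant members were Mir132 at 108.4 CPM (log2 ratio 0.30), which is not restricted to nervous tissue, and Mir598 at 55.3 CPM (log2 ratio 0.79), and the other 6 were below 10 CPM. Of the 8 genes, Mir218-1 (log2 ratio 0.68) and Mir218-2 (log2 ratio 0.78) are copies that share a window, and Mir212 and Mir132 form a cluster. The 8 genes are therefore not independent, and the range of random lists may be too narrow. The median without the copies was not computed. How many of the 13 genes muscle itself expresses is not known from these data. The list fixed before stayed inside random lists (median 0.59), and the Mir124a and Mir9 genes cannot decide because their precursors share sequence between copies.

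RNA of liver in replicate 1 is a candidate source of the excess of Mir122. Mir192, also known from liver, had a log2 ratio of -0.39 (62 and 53 reads, exact adjusted p = 0.276), and Mir194-2 of -0.10 (20 and 21 reads). Mir194-2 also shares a window with its copy Mir194-1, so its reads may have been set aside and its ratio cannot decide. Counts this low leave the source open, and the higher Mir205 and Mir200c of replicate 1 are not liver miRNAs. Beyond these sources of RNA from other tissues, no biological explanation was tested, since the design has a single group.

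The lower level of Dlk1-Dio3 miRNAs in replicate 2 was small and spread over the region. Reads aligned to several places were more frequent in replicate 2. The 48 members with no shared window had a median log2 ratio of -0.18, below random lists of such genes (-0.12 to 0.01), with 38 of 48 lower. This argues only against reads shared with other annotated precursors as the cause. Just 4 members share such a window, so the test nearly repeats the main result. Identical sequence elsewhere in the genome was not searched, so reads aligned to several places stay open as an explanation. Against random lists matched on the GC content of precursors, the median of the list, -0.16, also lay below the range (-0.13 to 0.06, percentile 0.32), which argues against GC content as the whole cause. Both sets of random lists draw genes from many loci, so their ranges may be too narrow for neighbours in a cluster. A difference in muscle maturity or cell composition between the animals stays open and untested, since both have the same age, sex and strain labels.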
